A study of Mus musculus with 24 samples.

How the data were processed

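RNA from the anterior cingulate cortex of 24 male mice was measured on Illumina whole-genome mouse bead arrays, one array per mouse, after extraction with a lipid tissue kit, amplification and biotin labelling, per the labels' protocols. The labels place 6 mice in each of 4 groups, sham or cuff surgery at 2 or 8 weeks, and the series design calls them biological replicates. The authors deposited a scanner table of intensity values per probe with a detection p-value for each probe and array, read out with GenomeStudio 2011.1 per the submitters' processing notes. Its values are linear, not normalized between arrays and not background-subtracted, as the columns show: the median raw intensity ran from 72.0 to 101 and the 95th percentile from 1258 to 2790. The authors also deposited a second table of intensity values on a linear scale, whose columns share an upper quartile and keep the probe order of the scanner columns (Spearman 1), with column medians between 87.8 and 87.9. It is thus quantile normalized by its values, a step not given in the sources used here, and was used as an alternative. The statistical test of the authors is not given in the sources used here.

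The scanner intensities were corrected for background with normexp from the detection p-values (limma 3.58.1 in R 4.3.3, offset 16), quantile normalized and taken to log2. A probe was kept with a detection p-value under 0.05 on at least 6 arrays, which left 22456 probes. Probes were named through the platform's annotation: 34885 of 45281 had 1 gene symbol, 18 had several and 10378 had none, and 34807 were found by Entrez ID in a RefSeq gene table, with 0 symbols changed. The brightest kept probe stood for a gene, and 4757 of the 11816 genes tested had more than 1. Where another probe of a named gene disagreed in sign, the text says so. Some items were not analysed here. No genome build was named, so no coordinates are given. A gene not well above background on any array of a group has only a bound, taken against the higher of its own value and the lowest detected signal of each array.

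Group means were fitted over all 24 arrays with limma's lmFit and eBayes (trend and robust), and adjusted p-values are Benjamini-Hochberg values over all genes of a comparison, two-sided, with a threshold of 0.05. Comparisons were cuff against sham at each time, their difference and their average, and 8 against 2 weeks within sham and within cuff. 25 gene lists were tested with camera (preset correlation 0.01, and estimated from the data) and fry, which asks whether a list's genes move one way on balance, adjusted over the lists of a comparison. The comparisons, the lists and the rule for named genes were set before the data were examined. So were the alternatives, except those with inferred slide, tissue covariates, exact permutation of per-array list means and without the arrays of highest and lowest raw signal, which were added after. The rule took the 12 genes past the threshold with the largest change in each direction of a comparison, filled to 10 per direction by smallest p for cuff against sham within a time and for the difference, the 4 members of smallest p of each list discussed and any passing over the list alone, and a fixed set of genes at both times.

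The steps were tested on simulated data with the arrays' own means and spread: of genes changed by 1 on the log2 scale 94% were recovered for cuff against sham at 2 weeks and 97% at 8 weeks, and of those changed by 0.5, 68% at both, over 11816 genes. Beside them 14 genes at 2 weeks and 8 at 8 weeks were called falsely. The simulation changed 100 genes of each size at once, with noise independent between genes, and recovery with fewer changed genes was not simulated. These shares therefore do not carry over to the real comparisons. In the real data at 2 weeks Egr2 (1.75) passed, while Arc (1.18), Dusp1 (1.13), Junb (1.11) and Fos (1.11) did not. With no change simulated, 0 genes were called. The files name no slide. The 17190 probes detected on no array grouped the arrays into 4 clusters of 6, each with mice of all 4 groups, and these were used as inferred slides after the data were examined. They are tentative, since neither the odd-numbered nor the even-numbered probes alone gave the same clusters. Alternatives covered background correction, normalization, offset, filter, probe summary, moderation, array weights, the samples in the fit, inferred slide, tissue covariates and leaving out each mouse. With other normalizations each gene kept its main probe.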

Results

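Gene expression was measured in the anterior cingulate cortex, a frontal midline region with roles in the affective side of pain and in mood, of male C57BL/6J mice. The mice had either a cuff placed around a nerve, a model of neuropathic pain, or a sham operation. Tissue was taken 2 or 8 weeks later, which gave 4 groups of 6 mice and 24 arrays. The series title places the study in neuropathic pain-induced depression. Each array carried 45281 probes, of which between 20067 and 21715 were detected per array, and 11816 genes entered the tests. Arrays of one group correlated at r between 0.982 and 0.996, arrays of different groups at r between 0.979 and 0.995, and no pair held identical values. The number of arrays per group limits the precision: the median standard error of a log2 fold change between groups at one time was 0.112.

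Cuff mice 2 weeks after surgery had higher RNA levels of immediate early genes, which neurons switch on within minutes of activity. Egr2, a zinc finger transcription factor, rose from a log2 intensity of 8.39 ± 0.54 (SD, n = 6) in sham to 10.14 ± 0.21 (SD, n = 6) in cuff mice, a log2 fold change of 1.75 (SE 0.30, adjusted p = 0.041), and all 6 cuff mice lay above all 6 sham mice. Csrnp1, a nuclear protein encoded by an early response gene, rose by 0.90 on the log2 scale (SE 0.14, adjusted p = 0.0124). These 2 were the genes past the threshold over all genes, both higher in cuff, and 98 genes had an unadjusted p under 0.01, where chance gives 118.2.

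Of the 22 measured members of the immediate early list, 20 had a positive log2 fold change at 2 weeks, with a mean of 0.52. Over all genes 2 members passed, and 12 passed when adjusted over the list alone. Beside Egr2 and Csrnp1 these were Egr4 (0.78, SE 0.17), Junb (1.11, SE 0.26), Fos (1.11, SE 0.30), Arc (1.18, SE 0.33), Gadd45b (0.51), Fosb (0.71), Egr3 (0.28), Egr1 (0.22), Fosl2 (0.32) and Ccn1 (0.94), the last detected on only 2 sham arrays. The list passed camera with a preset correlation (adjusted p = 1.96e-18) and with the correlation between its genes estimated (adjusted p = 0.023 with an estimated correlation). An exact permutation of the per-array list means gave p = 0.00216, the smallest that 6 arrays against 6 allow, and 0.0541 after adjustment over the 25 lists. Dusp1, the phosphatase MKP-1 that switches off MAP kinases, had a log2 fold change of 1.13 (SE 0.23, adjusted p = 0.173), which did not pass over all genes although all 6 cuff mice lay above all 6 sham mice. In the list of ERK feedback inhibitors, 0 of 14 members passed over all genes. Limma gave 576 genes at an unadjusted p under 0.05, where chance gives 590.8 in every comparison. Dusp1, Dusp6 (0.33) and Spry4 (0.44) passed when adjusted over the list alone. The list itself did not pass camera (adjusted p = 0.339), and its mean of 0.079 and median of -0.036 differed in sign.

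**Figure D1:**
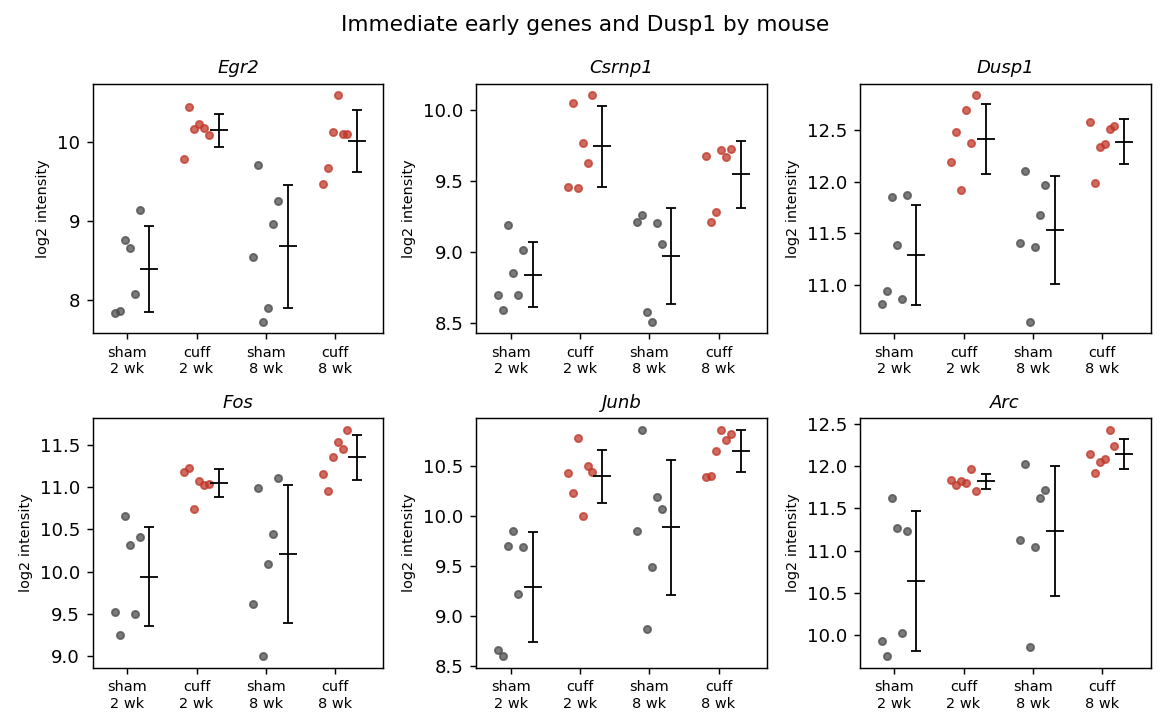
Log2 intensity (vertical axis) of 6 genes in each mouse (points) of the 4 groups (horizontal axis), with the group mean and SD as black bars. For Arc at 2 weeks the SD was 0.82 in sham and 0.085 in cuff mice, while for Csrnp1 it was 0.23 in sham and 0.28 in cuff mice.

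Further genes with the smallest p at 2 weeks did not pass. On the higher side these were Nfkbid (0.39), Grasp (0.38), Gadd45g (0.56), a growth arrest and stress response gene, and P4ha1 (0.36), a collagen prolyl hydroxylase subunit. On the lower side, the log2 fold changes were -0.60 for Nodal and -0.49 for Acan, the core protein of perineuronal nets, which were detected on only 2 and 1 cuff arrays, -0.51 for Epm2a, -0.48 for Ptprn2, -0.39 for Fan1, -0.36 for Tmem86b, -0.31 for Zfp638 and -0.25 for 4930445K14Rik, with 1 other probe of Epm2a and of Tmem86b of opposite sign. Il7r and Tti2 were not well above background on any cuff array, which leaves the sham mean at least 1.12-fold and at least 1.05-fold higher. These bounds allow for background only and not for the spread between mice, and neither gene passed. Slides inferred from unexpressed probes held equal numbers of cuff and sham arrays at each time, so the slide as a block left fold changes as they were and Egr2 and Csrnp1 as the 2 genes past the threshold. The count of 2 fell to 1 without cuff replicate 1, 3 or 5 or sham replicate 3 or 4, and to 0 without cuff replicate 2, 4 or 6 or sham replicate 1, 2 or 5.

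At 8 weeks, the immediate early genes again had higher values in cuff mice, but no single gene passed over all genes. All 22 measured members of the list had a positive log2 fold change, with a mean of 0.54. Over all genes 0 members passed with limma, where 470 genes had an unadjusted p under 0.05 and chance gives 590.8. Adjusted over the list alone, 15 members passed. Their log2 fold changes were 0.56 for Fosl2 (SE 0.11), 1.33 for Egr2 (SE 0.30), 0.70 for Egr4, 0.57 for Csrnp1, 0.59 for Sik1, 1.15 for Fos, 0.27 for Egr1, 0.31 for Egr3, 1.22 for Ccn1, 0.70 for Fosb, 0.76 for Junb, 0.91 for Arc, 0.40 for Gadd45b, 0.51 for Nr4a2 and 0.47 for Klf4. Sik1 and Ccn1 were detected on only 2 and 3 sham arrays and Klf4 on 5. The list passed camera (adjusted p = 1.33e-24, and adjusted p = 0.0055 with an estimated correlation), and the exact permutation of array means gave p = 0.00433, or 0.108 after adjustment. Dusp1 had a log2 fold change of 0.86 (SE 0.23, adjusted p = 0.709), and Dusp1, Dusp6 and Dusp5 passed when adjusted over the list of ERK feedback inhibitors alone, beside 0 of its members over all genes.

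Over all genes the smallest adjusted p at 8 weeks was 0.146, and 93 genes had an unadjusted p under 0.01. Further genes with the smallest p, none of which passed, were Klf2 (0.60), a Krüppel-like transcription factor of endothelium, Tekt1 (0.50) and Amotl2 (0.48) on the higher side. The negative log2 fold changes were -0.55 for Rab13, -0.53 for Gm5771, -0.51 for Dynll2, a dynein light chain, -0.46 for Atp2b4, a plasma membrane calcium pump, -0.44 for Pigk, -0.43 for Ticam1, -0.40 for Il17d, -0.36 for Blmh and -0.28 for Ddx6. Gm5771 and Ticam1 were detected on only 3 and 2 cuff arrays and Tekt1 and Amotl2 on 5 and 3 sham arrays. Another probe of Ddx6 had the opposite sign. Ankrd7, detected on only 3 sham arrays, was not well above background on any cuff array, which leaves the sham mean at least 1.08-fold higher. This bound does not allow for the spread between mice, and Ankrd7 did not pass. With the inferred slide as a block the count at 8 weeks stayed at 0, and with array weights 5 genes passed, 3 higher and 2 lower.

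Averaged over both times, 503 genes had an unadjusted p under 0.05 by limma, where chance gives 590.8. Past the threshold, 12 genes rose in cuff mice and 0 fell. They were Egr2 (1.54, SE 0.21), Fos (1.13, SE 0.21), Dusp1 (0.99, SE 0.16, adjusted p = 0.0106), Egr4 (0.74), Csrnp1 (0.74), Klf2 (0.52), Gadd45g (0.47), Fosl2 (0.44), P4ha1 (0.33), Nfkbid (0.33), Sntb2 (0.32) and Dusp6 (0.29). Of the immediate early list, 5 members passed over all genes and 17 passed when adjusted over the list alone, which adds Junb (0.94), Egr3, Egr1, Fosb, Gadd45b, Arc (1.04), Sik1, Ccn1, Npas4, Klf4, Nr4a2 and Jun. The list mean was 0.53 higher in cuff (SE 0.09), and also 0.53 with the inferred slide as a block (SE 0.08). Within the 8 pairs of inferred slide and time, the difference was positive in 7, from -0.081 to 0.97 (exact sign-flip p = 0.0156, two-sided). The list kept its call with an estimated correlation (adjusted p = 0.000476), and the exact permutation of array means gave an adjusted p of 0.000117. With the inferred slide as a block 17 genes passed, and without sham replicate 3 at 2 weeks 20 passed. Leaving out each of the 24 mice in turn, Fos lost its call 15 times, Dusp6 14 times and Sntb2, with 2 other probes of opposite sign, 11 times, and the other 9 genes kept theirs.

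**Figure D2:**
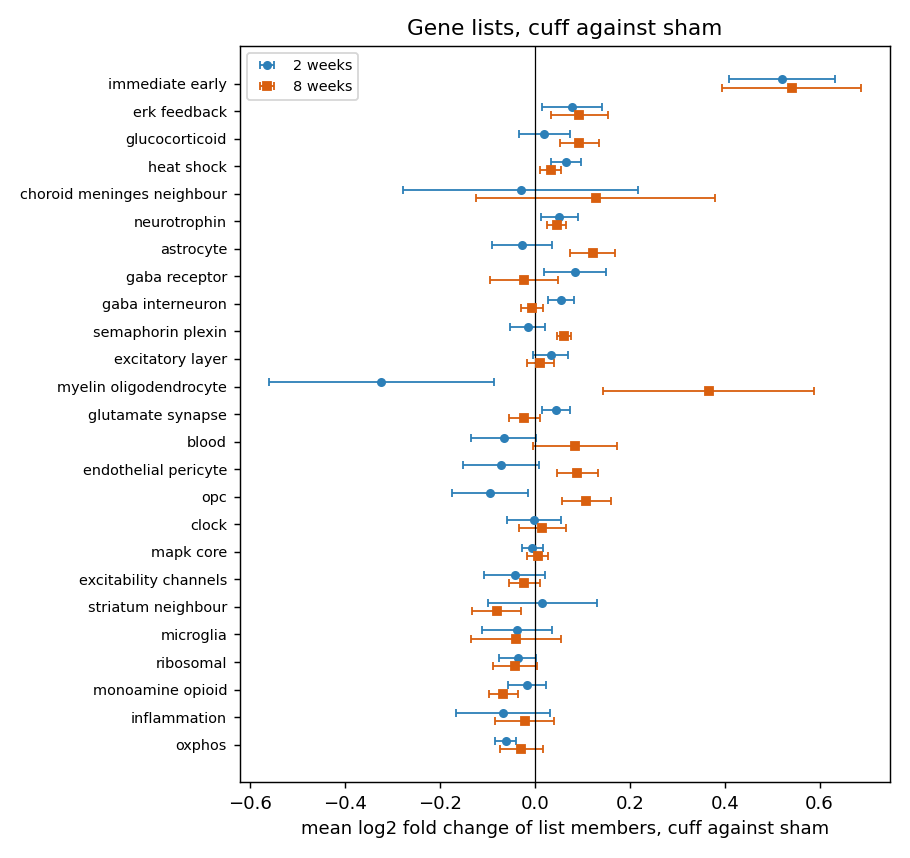
Mean log2 fold change of cuff against sham (horizontal axis) of the measured members of each of 25 gene lists (vertical axis) at 2 weeks (circles) and 8 weeks (squares), with the standard error between arrays as bars. The immediate early list stands at 0.52 and 0.54, and the myelin list at -0.32 and 0.37 with wide errors.

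The cuff effects at both times, which share no arrays, were compared over all genes. They did not correlate across genes, which are not independent replicates (Pearson r = -0.044, permutation p = 0.861; Spearman rho = -0.053, permutation p = 0.752). A small set of genes was higher at both: 18 genes had an unadjusted p under 0.01 and a positive value each time, against 0.25 expected for independent lists (permutation p = 0.0198, 100 permutations). Of these 18, 9 were on the immediate early list (Csrnp1, Egr1, Egr2, Egr3, Egr4, Fos, Fosb, Fosl2 and Junb), and the others were Dusp1, Dusp6, Gadd45g, Klf2, Nfkbid, P4ha1, Sntb2, Tob1 and Amigo3. There were 0 genes lower at both times and 0 in opposite directions by limma at that threshold. Without sham replicate 3 at 8 weeks, 10 genes were higher at both.

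**Figure D3:**
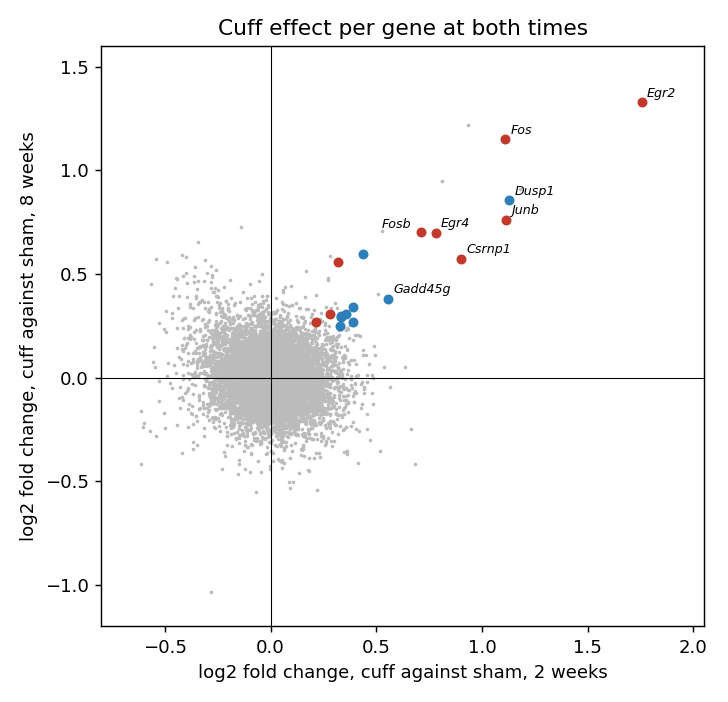
Log2 fold change of each gene (grey points) for cuff against sham at 2 weeks (horizontal axis) and 8 weeks (vertical axis). The 18 genes with an unadjusted p under 0.01 and a positive value at both times are coloured, red for the 9 on the immediate early list and blue for the other 9.

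Myelin and oligodendrocyte genes had opposite signs at the 2 times. At 2 weeks 26 of 27 measured members had a negative log2 fold change (mean -0.32). Values were -0.53 for Cnp, -0.57 for Fa2h, -0.40 for Ndrg1 and -0.37 for Gsn, which was detected on 5 of 6 cuff arrays and had another probe of opposite sign. By limma 0 passed over all genes or adjusted over the list alone, beside 576 of all genes at an unadjusted p under 0.05. At 8 weeks all 27 had a positive one (mean 0.37). Values were 0.59 for Mal, 0.50 for Ndrg1, 0.49 for Tspan2 and 0.30 for Olig1. Again 0 passed either way by limma, beside 470 of all genes at an unadjusted p under 0.05. Camera called the list at both times with the preset correlation, and neither call was kept (at 2 weeks adjusted p = 0.652 and at 8 weeks adjusted p = 0.419 with an estimated correlation). Mice of one group differed widely, with an SD of the list mean of 0.48 in cuff mice at 2 weeks and 0.51 at 8 weeks, and within inferred slides the differences went both ways.

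**Figure D4:**
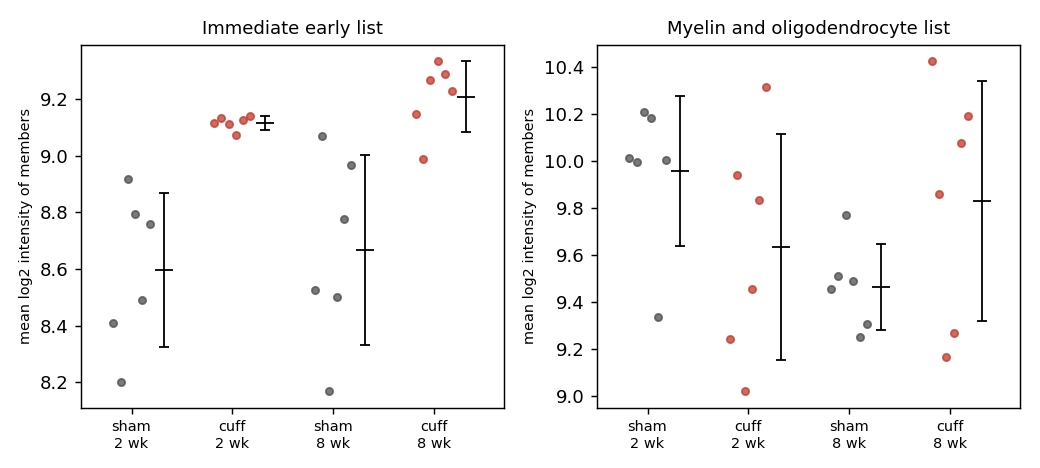
Mean log2 intensity (vertical axis) of the 22 immediate early genes and of the 27 myelin genes in each mouse (points) of the 4 groups (horizontal axis), with the group mean and SD as black bars. The immediate early mean had an SD of 0.024 in cuff mice at 2 weeks and 0.27 in sham mice, while the myelin mean overlapped between groups.

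The difference between the cuff effects, 8 weeks minus 2 weeks, was tested in the same fit. With limma 0 genes passed, and 552 had an unadjusted p under 0.05, where chance gives 590.8. The smallest adjusted p was 0.988. The genes with the smallest p, which did not pass, were Itga6 (0.85), Ndrg1 (0.90), the nuclear RNA Neat1 (0.88), Padi2 (0.78), Folh1 (0.75), Ddc (0.74), Erbin (0.66), Cxcl12 (0.43), Ubl3 (0.39) and Kif5a (0.36) with positive values. Those with negative values were Gm5771 (-0.62), Dynll2 (-0.61), Atp2b4 (-0.60), Cort (-0.51), the neuropeptide cortistatin, Bhlha9 (-0.51), Blmh (-0.46), Msto1 (-0.45), Sergef (-0.44), Ppp1r1a (-0.43) and Grasp (-0.42). 1 other probe of Itga6, Padi2, Dynll2 and Blmh and 2 of Cxcl12 had the opposite sign, and Gm5771 was detected on 1 array of each 2-week group. Cort passed adjusted over the list of interneuron genes alone, beside 0 of 20 over all genes. The myelin list differed by 0.69 on average between the times (camera adjusted p = 5.44e-19, and adjusted p = 0.495 with an estimated correlation), with Ppp1r14a (1.05), Mal (1.01) and Adamts4 (0.75) among its members.

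Other lists called by camera lost the call once the correlation was estimated. At 2 weeks these were the oxidative phosphorylation genes (37 of 46 negative, adjusted p = 0.565 with an estimated correlation), with -0.23 for Ndufa5, -0.13 for Ndufa4, -0.14 for Uqcrh and -0.13 for Uqcrc2. At 8 weeks the astrocyte list had 21 of 23 members positive (adjusted p = 0.226 with an estimated correlation), with 0.39 for Glul, 0.25 for Ppp1r3c, 0.20 for Gja1 and 0.19 for Gjb6. The glucocorticoid list had 16 of 22 positive (adjusted p = 0.226 with an estimated correlation), with 0.36 for Sgk1 and 0.27 for Nr3c1. Nr3c1 was detected on 1 sham array. The endothelial and pericyte list had 19 of 24 positive (adjusted p = 0.443 with an estimated correlation), with 0.26 for Flt1 and 0.26 for Pecam1. The ribosomal protein list had 28 of 36 negative (adjusted p = 0.559 with an estimated correlation). For the average of both times the calls lost were oxidative phosphorylation (adjusted p = 0.403 with an estimated correlation), ribosomal proteins (0.568), heat shock (0.264) and astrocytes (0.519). The microglia list did not pass camera at 2 weeks (adjusted p = 0.364) or 8 weeks (0.322), nor did the inflammation list (0.364 and 0.67), the glutamate synapse list (0.155 and 0.511) or the interneuron list (0.155 and 0.888).

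Among genes fixed for reporting at both times, the log2 fold changes at 2 and 8 weeks were 0.21 and 0.11 for Bdnf, -0.12 and -0.15 for Fkbp5, -0.39 and 0.25 for Mbp, -0.40 and 0.29 for Mog, -0.22 and 0.24 for Gfap, -0.12 and -0.08 for Aif1, -0.30 and 0.07 for Pvalb, 0.06 and 0.03 for Sst and 0.18 and -0.14 for Sema4a. Sgk1 had 0.06 at 2 weeks, and none of these genes passed. Leaving out 1 mouse brought Gfap to -0.025, Pvalb to -0.12, Mog to -0.24, Bdnf to 0.12, Fkbp5 to -0.058, Aif1 to -0.065 and Sst to 0.0097 at 2 weeks. At 8 weeks it brought Mog to 0.095, Bdnf to 0.042, Mbp to 0.17, Fkbp5 to -0.091 and Sema4a to -0.071. The sign changed for Sgk1 at 2 weeks and for Aif1, Pvalb and Sst at 8 weeks. Another probe of Gfap at 2 weeks, another of Mbp and 2 others of Bdnf at 8 weeks had the opposite sign.

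In sham mice, haemoglobin genes were lower at 8 weeks than at 2 weeks. Hba-a1 fell by 0.62 on the log2 scale (SE 0.10, adjusted p = 0.00899), from 14.12 ± 0.16 to 13.50 ± 0.20 (SD, n = 6 each), Hbb-bt fell by 0.55 and Hbb-bs fell by 0.50. Gm5771 (0.61), Pik3r3 (0.56), a regulatory subunit of phosphoinositide 3-kinase, Zfp316 (0.55), Il17d (0.50) and Trappc3 (0.47) rose. These 8 genes, 5 higher and 3 lower, were those past the threshold, with Gm5771 detected on 1 array at 2 weeks and 6 at 8 weeks, and 629 genes had an unadjusted p under 0.01. Of the 7 measured red blood cell genes, 3 fell over all genes and 5 when adjusted over the list alone, which adds Alas2 and Slc4a1, the latter detected on 2 arrays at 8 weeks (adjusted p = 0.277 with an estimated correlation, 0.00626 with fry and 0.0271 by exact permutation of array means). All 27 myelin genes had a negative value (mean -0.49; adjusted p = 0.523 with an estimated correlation), with -0.81 for Mal, -0.60 for Cryab, -0.57 for Gsn, detected on 3 arrays at 8 weeks, and -0.37 for Olig1. Gsn passed adjusted over the list alone, beside 0 of the list over all genes with limma, where 1923 genes had an unadjusted p under 0.05. The oligodendrocyte precursor list had 12 of 14 members negative (adjusted p = 0.29 with an estimated correlation, 0.0586 with fry and 0.0271 by exact permutation of array means), with -0.32 for Gpr17, -0.45 for Sox10 and -0.26 for Pdgfra but 0.39 for Cspg5, and Gpr17 and Cspg5 passed adjusted over the list alone, beside 0 over all genes. 1 other probe of Pdgfra and of Cspg5 had the opposite sign. The endothelial and pericyte list had 18 of 24 negative (adjusted p = 0.452 with an estimated correlation), with -1.28 for Acta2, -0.36 for Flt1, -0.39 for Cldn5 and -0.51 for Myl9, of which Flt1 and Acta2 passed adjusted over the list alone, beside 0 over all genes, and Myl9 had -0.27 with 1 mouse left out. The choroid plexus and meninges list had 17 of 18 negative (adjusted p = 0.523 with an estimated correlation).

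The count of 8 with time in sham was 1 without sham replicate 2, 4 without replicate 3 and 5 without replicate 5 at 8 weeks, and 5, 4, 19 and 5 without replicates 2, 3, 4 and 6 at 2 weeks. It was 44 with the inferred slide as a block, 84 with only the sham arrays in the fit and 0 with myelin and meninges means as covariates.

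In cuff mice, 621 genes differed between 8 and 2 weeks, 298 higher and 323 lower. Those that rose most were ND6 (0.95, SE 0.17), a mitochondrially encoded subunit of complex I, Lbh (0.90), Sf3a2 (0.73), Folh1 (0.71), Psme3 (0.69), Il33 (0.69), an alarmin cytokine, Scaf1 (0.68), Trim59 (0.68), D730003I15Rik (0.65), 2610035D17Rik (0.65), Hsf4 (0.65) and Asb16 (0.64). Those that fell most were Car12 (-0.95, SE 0.19), a carbonic anhydrase, C2cd4a (-0.83), Serpinf1 (-0.82), Slc38a5 (-0.76), Otub2 (-0.75), Col23a1 (-0.71), Retsat (-0.69), Tmie (-0.66), Sdf2l1 (-0.66), Megf11 (-0.65), Cd3e (-0.64) and Hspb1 (-0.64). Sf3a2 was detected on 1 array at 2 weeks and Col23a1 on 5 at 8 weeks, and 1 other probe of Serpinf1, Retsat and Megf11 had the opposite sign. Of the heat shock and unfolded protein response list, 4 of 29 members fell over all genes (Sdf2l1, Xbp1, Hspb1 and Chordc1). Adjusted over the list alone, 9 fell, adding Pdia4, Calr, Hspb8, Dnajb1 and Ddit3, and 3 rose, Hspa1a (0.41), Hsp90b1 (0.24) and Bag3 (0.30). The list as a whole did not pass camera (adjusted p = 0.508), with a mean of -0.083 and a median of 0.020. Hbb-bs fell by 0.33, and Hbb-bt (-0.29) and Hba-a1 (-0.28) passed adjusted over the red blood cell list alone, beside 1 of 7 over all genes. Of the semaphorin and plexin list, Sema4a (-0.32), Plxna2 (-0.28) and Sema3f (-0.44) passed adjusted over the list alone, beside 0 over all genes with limma (2693 genes at an unadjusted p under 0.05).

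The count of 621 moved more with single mice than any other. It was 8 without cuff replicate 6, 48 without replicate 2, 142 without replicate 4, 197 without replicate 5, 1355 without replicate 3 and 1572 without replicate 1 at 2 weeks, and 182, 350, 290, 31 and 83 without replicates 1, 2, 3, 5 and 6 at 8 weeks. At 2 weeks this order was that of the first principal component of all arrays. Cuff replicates 6, 2, 4 and 5 scored 25.9, 21.6, 17.5 and 12.6 on it, and replicates 3 and 1 scored -8.29 and -8.40. All arrays at 8 weeks scored negative, as replicates 3 and 1 did. Among the 2-week mice the count thus rested on replicates 6, 2, 4 and 5. It also fell to 31 and 83 without replicates 5 and 6 at 8 weeks, which the order at 2 weeks does not cover. With the inferred slide as a block 1028 genes passed, and with median centring 169 did, 158 higher and 11 lower. The larger count in cuff than in sham is not by itself a difference between them: 0 genes passed the test of that difference with limma, which equals the test of the difference between the cuff effects.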

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

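The tests of slide, of myelin genes moving together, of the spread between mice and of the genes higher at both times over other splits were chosen only after the result was seen. A fit with the inferred slide as a block decides nothing about slides as the source of the cuff effects, because slides hold equal numbers of cuff and sham arrays at each time and the block cannot move those effects. It is the balance itself that keeps a shift shared by a slide out of the cuff effects, as far as the inferred slides are right. Differences within slides add nothing to that.

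The myelin genes stood out because their cuff effect differed between the times (camera adjusted p = 5.44e-19), as did those of the astrocyte (0.00892) and endothelial lists (0.00229). None of these calls was kept with an estimated correlation (0.495, 0.519 and 0.495). Within groups the myelin genes rose and fell together, with an estimated correlation of 0.782, which is in line with a share of white matter that varies between tissue pieces. With myelin and meninges means as covariates the difference had a limma camera adjusted p of 0.978, as the construction of that covariate requires. Within inferred slides, with signs turned at 2 weeks, 5 of 8 differences were positive (mean 0.29, exact sign-flip p = 0.219). Each inferred slide holds equal numbers of cuff and sham arrays at each time, so a shift shared by its arrays cannot produce the difference, as far as the inferred slides are right. A change in oligodendrocytes with time after nerve injury stays open and untested.

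The immediate early genes were weighed against technical explanations. The balance of cuff and sham over the inferred slides argues against a shift shared by the arrays of a slide, as far as the inferred slides are right. Within them the difference averaged 0.495 (exact sign-flip p = 0.0156), which adds nothing to that argument. With myelin, meninges, astrocyte and endothelial means as covariates the list mean still differed by 0.508 (SE 0.107), which argues against differing shares of these tissue components. Neuronal, cortical layer and striatal means were not entered, so other differences in composition were not tested. The lowest value without 1 mouse was 0.481 (sham replicate 3 at 8 weeks), which argues against a single array. The order and handling of the mice at tissue collection are not given in the sources used here. These genes respond within minutes, so a difference in handling may also produce the pattern. An effect of nerve injury on cingulate activity stays open beside it.

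More genes passed with time in cuff than in sham mice. Of the 621 genes in cuff, 96% had the same sign in sham, against 68.8% of all genes, with a median ratio of sham to cuff change of 0.535. Over all genes, which are not independent, the time effects correlated at r = 0.511, and these values argue against a time course of opposite or unrelated direction in sham. At an unadjusted p under 0.05, 103 of them differed between cuff and sham, where chance gives 31, but the genes were picked in cuff, which enlarges that number. The inferred slides were not balanced over time. Slides 1 and 2 each held 2 cuff and 2 sham arrays of 2 weeks and 1 of each of 8 weeks, and slides 3 and 4 the reverse. With the inferred slide as a block the count was 1028, which argues against slides as its cause, as far as the inferred slides are right. The share of genes with the same sign and the correlation were not adjusted for slide. Age, cohort and time since surgery were not separated by the design.

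Chance could not be excluded for the count at 2 weeks, since 8 of the 100 splits gave at least the real value of 2 and the highest other gave 1698. At 8 weeks (highest other 0) and for the difference of the cuff effects (highest other 204) the real value was 0, which all 100 of the 100 splits reach by definition, so the splits decide nothing there. Few splits, counted with the real one, gave as many genes for the average of both times (1 of the 100 splits, 12 against 6 for the highest other). The same held for time in sham (3 of the 100 splits, 8 against 152) and for time in cuff (2 of the 100 splits, 621 against 755). In each time comparison at least 1 other split gave more genes, and leaving out 1 mouse took the real counts as low as 1 and 8. Few splits also reached the immediate early members adjusted over the list alone at 2 weeks (1 of the 100 splits, 12 against 9) and 8 weeks (2 of the 100 splits, 15 against 15, a tie). For the genes higher at both times it was 1 of the 100 splits (18 against 8), though in the separate permutations behind the agreement test another 1 reached 18. These ranks make chance less likely for each count without excluding it. The split with 1698 genes followed the first principal component among the mice at 2 weeks (absolute r of 0.804), which points to a structure of those samples. That with 755, among the cuff mice of both times, had an absolute r of 0.727 with the component. That with 152, among the sham mice of both times, had 0.135. For the split with 204 genes no such value was taken. What the component reflects was not tested.

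Of 720 values tested within groups, 30 had 1 mouse far from the other 5, or 4.17%, and chance gives about 1 in 20. The measure is the gap to the nearest mouse over the range. In sham mice at 2 weeks, replicate 3 was high for the inflammation (0.779), endothelial (0.794) and choroid plexus and meninges lists (0.682) and for Dusp6 (0.672), Zfp638 (0.765), Acta2 (0.674) and Myl9 (0.767). Replicate 5 was low for the myelin list (0.755), Mog (0.636) and Folh1 (0.854), while replicate 2 was high for the striatum list (0.772) and replicate 6 was low for Aif1 (0.718). In sham mice at 8 weeks, replicate 2 was high for Blmh (0.635), Nr3c1 (0.646) and Pdia4 (0.755) and low for Cldn5 (0.686), and replicates 3, 4 and 6 were low for the cortical layer list (0.633), Grasp (0.654) and Xbp1 (0.643). In cuff mice at 2 weeks, replicate 3 was low for Egr1 (0.719) and high for Cort (0.728), replicate 6 was high for Ndrg1 (0.648) and replicate 2 for Pigk (0.628). In cuff mice at 8 weeks, replicate 1 was high for the glucocorticoid (0.749) and semaphorin lists (0.677), Uqcrh (0.653) and Arrdc2 (0.823), replicate 5 for the endothelial list (0.673), replicate 4 for Bdnf (0.742) and replicate 2 for Sdf2l1 (0.804).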

How the results depend on the processing

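The alternatives with the inferred slide, covariates, permutation of list means and without the arrays of highest and lowest raw signal were chosen after the result was seen. No paired analysis was possible because each mouse gave 1 array and no label pairs mice, and the only matching run was by inferred slide, with p = 0.0156 for the immediate early list (exact sign-flip). The planned slide block was not run as planned, since the files name no slide. The cause was not tested for any change below unless given.

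With cyclic loess, an offset of 50, no background correction or the authors' table, every count of genes and lists stayed within 1.5 times its value. For cuff against sham at 2 weeks (2 genes) the count was 1 with median centring, no filter or covariates and 0 with array weights or without the extreme arrays, and 0 to 2 leaving out 1 mouse. At 8 weeks (0 genes by limma, 470 at an unadjusted p under 0.05) it was 1 without trend and 5 with array weights. For the average (12) it was 6 with median centring or without the extreme arrays, 19 with every probe, 23 with array weights, and 9 to 20 leaving out 1 mouse (20 without sham replicate 3 at 2 weeks).

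For time in sham (8) it was 20 with every probe, 4 with array weights, 84 with only the sham arrays, 44 with slide, 0 with covariates, 3 without the extreme arrays, and 1 to 19 leaving out 1 mouse. For time in cuff (621) it was 169 with median centring (158 higher, 11 lower), 313 with no filter, 230 with probe means, 329 without trend, 2313 with array weights, 1028 with slide, 1074 with covariates, and 8 to 1572 leaving out 1 mouse. Genes higher at both times (18) were 8 with median centring, 30 at an unadjusted p under 0.05, and 10 to 21 leaving out 1 mouse.

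Lists called at 2 weeks (3) were 5 with stricter detection or without the extreme arrays, 7 with every probe, 1 with an estimated correlation or fry, 0 by permutation, and 3 to 6 leaving out 1 mouse. At 8 weeks (6) they were 10 with every probe, 3 with array weights, 1 with covariates, an estimated correlation or fry and 0 by permutation. For the difference (3) they were 5 with probe means or every probe, 0 with covariates, an estimated correlation, fry or permutation, and 1 to 5 leaving out 1 mouse. For the average (5) they were 3 with median centring or without the extreme arrays, 1 with an estimated correlation, fry or permutation, and 3 to 9 leaving out 1 mouse. For time in sham (5) they were 1 with covariates or fry, 0 with an estimated correlation and 2 by permutation, and for time in cuff (0) 1 with median centring, only the cuff arrays or slide, 2 with every probe, and 0 to 2 leaving out 1 mouse.

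The immediate early list had adjusted p = 0.0541 at 2 weeks and 0.108 at 8 weeks by exact permutation, where the smallest p of 6 arrays against 6 limits the adjusted value. The myelin list had p = 0.989, 0.652, 0.614 and 0.671 at 2 weeks with covariates, an estimated correlation, fry and permutation. In that order it had 0.944, 0.419, 0.412 and 0.329 at 8 weeks, 0.978, 0.495, 0.485 and 0.396 for the difference, and 0.943, 0.523, 0.152 and 0.0676 with time in sham.

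With covariates the sign changed for Mog at 2 weeks (0.0679) and 8 weeks (-0.218), Sst at 2 weeks (-0.0178), Mbp (-0.0633) and Pvalb (-0.187) at 8 weeks, for Mog and Mbp because the covariate holds them. It changed for Sst at 8 weeks with median centring (-0.0388), for Cxcl12 in the difference with probe means (-0.057), and leaving out 1 mouse gave -0.0129 to 0.189 for Sgk1 at 2 weeks and, at 8 weeks, -0.154 to 0.0544 for Aif1, -0.0642 to 0.167 for Pvalb and -0.00773 to 0.0769 for Sst. Over 4029 other comparisons 3741 kept direction and side of the threshold, 199 lost the call, 78 gained it and 11 changed sign. A result that had not passed in the main fit counts as kept when it again did not pass. Only results that had passed could be among the 199, so the share kept does not measure how stable the calls were. Signal over background limits the dim genes, such as Il7r and Ankrd7.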

Other observations

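The test of the spread was chosen only after the result was seen, and the tests of Dusp1 and of the genes off the list were set before it.

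Immediate early genes varied less among cuff than among sham mice. Arc, whose RNA travels to active synapses, had an SD of 0.824 in sham and 0.0852 in cuff mice at 2 weeks, and 0.766 and 0.175 at 8 weeks. The SD was smaller in cuff for 15 of the 22 list members at 2 weeks and 17 at 8 weeks, against 49.6% and 62.4% of all genes. The list mean lay closer to its group median in cuff by 0.197 on average (difference -0.197, permutation p = 0.000122, two-sided). The permutation relabelled deviations from the real group medians without taking new medians. Its p is thus approximate and may be too small. At 8 weeks the highest list mean in sham (9.07) lay above the lowest in cuff (8.99), while at 2 weeks the highest in sham (8.92) lay below the lowest in cuff (9.07). A candidate explanation is that sham mice differed in recent activity while cuff mice were all near the upper end, from injury or from handling. It was not tested.

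Genes off the list that were higher in cuff at both times followed the list mean among the 12 sham mice, each time centred. The median correlation of these 9 genes was 0.654, above the 95th percentile of 0.207 from 1000 random sets, with 0.926 for Dusp1, 0.868 for Nfkbid, 0.749 for Dusp6, 0.715 for Gadd45g, 0.654 for Sntb2 and 0.628 for Klf2. Tob1 (0.241), Amigo3 (0.111) and the prolyl hydroxylase subunit gene P4ha1 (-0.036) did not follow it closely. This is consistent with 1 activity program that also varies without nerve injury, and P4ha1 may lie outside it.

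Dusp1 is a phosphatase that ends MAP kinase signals and is itself induced by activity. Its average cuff effect of 0.992 fell to 0.199 with the immediate early list mean as a covariate (SE 0.161) in a least squares fit of all 24 arrays. At 2 weeks every list mean in cuff (lowest 9.07) lay above every one in sham (highest 8.92). The covariate thus tends to lower the cuff effect of any gene raised in cuff, and the fall alone does not tie Dusp1 to the program. Among sham mice Dusp1 did follow the list mean (r = 0.926). The data do not separate a cuff effect on Dusp1 alone from the program.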
